A study of Mus musculus with 3 samples.

How the data were processed

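Single-cell RNA libraries were made from the immune-enriched cells of liver tumours of MUP-uPA mice, which carry a plasminogen activator transgene in hepatocytes. Per the labels, a Western diet was given from 8 weeks of age for 8 months and tissue was taken at 10 months of age, when hepatocellular carcinoma had formed. Tumours were dissected, digested with collagenase I and DNase I, and enriched for immune cells on a density gradient, which can limit which cell types were recovered. All 3 libraries belong to 1 group and to 1 batch. The labels do not say that they came from separate animals, so p-values from sums per library measure only the spread between these libraries, which may be technical. Rank p-values place the Y genes among matched gene sets instead. Exact tests pool the libraries and cover counting error only.

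The authors deposited UMI counts per gene and cell barcode, made from 10x Genomics 3' reads with Cell Ranger 8.0.1 on the mm10 build, per the submitters' processing notes. A UMI is a molecular barcode that lets each captured RNA molecule be counted once. Seurat and Scanpy are also named in those notes, with no role given, and no cell type annotation was used here. Gene positions and biotypes came from the GENCODE vM21 annotation of GRCm38, the assembly behind mm10, which matched 32158 of the 32285 gene identifiers (99.6%). Coordinates are given from 1 at the start of each chromosome.

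Cells with at least 500 UMIs, at least 300 genes and at most 25% mitochondrial UMIs were kept. Scrublet, as built into scanpy 1.11.5, was run per library with an expected doublet rate of 0.8% per 1000 cells. Its automatic threshold marked 3, 1 and 1317 cells in libraries 1, 2 and 3, so it had not worked in the first pair of libraries. The expected share with the highest scores was removed instead, 523, 1139 and 1267 cells. Clusters whose median doublet score was above 0.12, a limit set after the data were seen, were also kept out of the cell classes. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 20 neighbours were used for Leiden clustering at resolution 1. Genes of the Y chromosome, Xist, Tsix and mitochondrial genes were left out of the variable genes. So were variable and joining segments of antigen receptors and most immunoglobulin constant genes, though not Igha, which made 1381 genes in all. A gene had to be seen in 10 cells. Clustering used Python 3.11.15 with leidenalg 0.10.2, igraph 0.11.9 and scikit-learn 1.9.0. A cluster took a class name from marker lists when at least 3 markers were detected at 2-fold over the other clusters and at 10 CPM, with an offset of 5 CPM. Class names mean cells like that type.

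Y transcripts were the sum of Ddx3y, Eif2s3y, Kdm5d and Uty. UMIs were summed per library and class, for classes with at least 20 cells in every library. Sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default filter on low counts and the library as a block. The library pairs the classes by construction, since each library holds all of them. Adjusted p-values follow Benjamini and Hochberg, over the contrasts for the summed Y genes and over all tested genes elsewhere. For cells without Y UMIs, each cell was thinned to 2000 UMIs, and the share at 0 was set beside the Poisson share of the same mean and beside 1000 sets of 4 autosomal genes matched on mean count within 20%. A class needed 100 such cells per library. Cells with an expected Y count of at least 5 were examined apart. Joint absence was the Mantel-Haenszel odds ratio that a pair of Y genes was detected in the same cell, over 10 depth bins and 6 gene pairs, beside 200 matched sets of genes on different chromosomes, for classes with at least 200 cells per library. Percentiles among matched sets describe these libraries, because genes are not replicates.

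Y-negative cells had 0 UMIs of the 4 Y genes and Y-positive cells at least 1, among cells with at least 1000 UMIs. Equal numbers of both were drawn from 10 bins of non-Y UMIs per library, with at least 50 cells of each in every library. The split is of cells by a measured status, and a cell with 0 Y UMIs is not shown to lack the chromosome. The same split was made with 20 sets of 4 matched autosomal genes per class. The 39 gene lists were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry, all in limma 3.58.1, when at least 3 members passed the filter. They were 17 gene lists (T cell exhaustion, cytotoxic effector, naive or memory, regulatory T, tissue residency, interferon response, MHC class I, MHC class II, cell cycle, dissociation and heat stress, DNA damage and p53, X copies of Y genes, liver secreted, liver tumour, lipid handling, ribosomal proteins, mitochondrial transcripts) and 22 marker lists of cell types and T cell states. Named genes were the 4 Y genes, the 6 X copies, the 10 largest rises and falls among genes with adjusted p under 0.05 and 1 direction in all 3 libraries, and up to 4 members per list with the smallest p. For clusters the 3 genes of largest fold gave the identity, and genes outside this rule are named as such. Some genes that the rule names are not reported here.

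Each statistic was tested on simulated data. In simulated T cell sums over 9899 genes, edgeR recovered 65.7% of changes of 1.5-fold, 83.6% of 2-fold and 98.5% of 4-fold, with 4.62% of calls false. In simulated monocyte or macrophage sums over 9007 genes it recovered 65.7%, 85.1% and 97.0%, with 5.71% false, and in simulated neutrophil sums over 3116 genes 25.4%, 62.7% and 92.4%, with 1.64% false. In simulated T cells the odds ratio of the 4 Y genes was 1.02 with no loss, 1.17 with the chromosome removed from 5% of cells and 1.72 with 20%. In simulated conventional dendritic cells it was 0.99, 1.19 and 1.92. Each gene was drawn independently at a class-wide rate, with no other variation between cells. These odds ratios therefore cannot turn an observed value into a share of cells with loss. Intervals are exact binomial or Poisson at 95%, a count of 0 was taken to allow up to 3 counts, and both cover counting error only.

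Before the data were examined, the tests, the lists, the naming rule and these alternatives were fixed: DESeq2 size factors, no normalization factors, no filter on low counts, DESeq2 1.42.0, no library block, the pair of highest Y genes alone, thinning to 1000 or 4000 UMIs, matching within 10%, 20 depth bins, at least 2000 UMIs, no depth matching, Y-positive at 2 UMIs, an expected Y count of 3, doublets kept, at most 10% mitochondrial UMIs, Leiden resolution 2, and each library left out. Matching Y-negative with Y-positive cells on cluster as well as depth, depth bins inside clusters, leaving out cells with UMIs of the T cell markers, and tests inside single T cell clusters were added after the data were seen. Further computations used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, with plots from matplotlib 3.10.9.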

Results

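Gene expression was measured in single immune-enriched cells from liver tumours of MUP-uPA mice on a Western diet, a model of fatty liver disease with hepatocellular carcinoma. The series asks about cells that lose the Y chromosome, both among cancer cells and among T cells. All 3 libraries form 1 group, so the comparisons were made between cell classes, and between cells with and without Y transcripts, inside each library. Libraries 1, 2 and 3 held 8096, 11941 and 12594 barcodes with 47859122, 67295833 and 78822518 UMIs, and median depths of 4305, 4309 and 4778.5 UMIs per cell. After filters and removal of doublets, 29674 cells were kept. Counts over genes differed between each pair of libraries by 61.7 to 83.6 times the sampling noise (chi-square per degree of freedom), so no library was a copy of another.

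The cells were leukocytes. T-like cells made up 34.1% ± 4.42 of cells (SD, n = 3), monocyte or macrophage-like cells 16.3% ± 4.11, B-like cells 15.4% ± 8.48, and NK or innate lymphoid-like cells 9.63% ± 3.55. Conventional dendritic-like cells held 7.24% ± 2.48, neutrophil-like cells 3.34% ± 0.979, plasmacytoid dendritic-like cells 3.34% ± 1.45, basophil or mast-like cells 0.631% ± 0.250 and Kupffer-like cells, the resident macrophages of liver, 0.178% ± 0.167. B-like cells took 25.2% of library 1 and 10.3% and 10.8% of libraries 2 and 3. The T-like cells fell into 9 clusters. The largest was led by Gzmk, a granzyme of CD8 T cells, with Epha3 and Coch, and held Pdcd1, the checkpoint receptor PD-1. Against the other T-like cells its largest folds were Igha, Spp1 and Jchain. Jchain is on the plasma cell list, and Spp1 is among the leading genes of a monocyte or macrophage-like cluster. RNA of other cells in this cluster was not tested. Other T clusters were led by the regulatory T cell genes Tnfrsf4 and Il1rl1, by the cytokine gene Il4 with Zbtb16, and by Gzmm. Further clusters were led by Igfbp4 and Dapl1, by the gamma-delta T cell gene Cd163l1 with Il23r, by Gzma with Klra1, by the cytokine genes Il17a, Il17f and Il22, and by the interferon-induced Ifit3 and Ifit1. The density gradient can shift these shares, which was not measured, and exact binomial intervals for each library cover counting error only.

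No cluster resembled hepatocytes, so tumour cells could not be compared with T cells. Of the 10 hepatocyte markers, at least 1 was seen in 6430 of 29674 cells (21.7%), at least 3 in 84 cells and at least 5 in 6 cells, and single hepatocytes outside a cluster of their own were not counted. Albumin (Alb), the main secreted protein of hepatocytes, gave 152, 98 and 148 UMIs in the 3 libraries, or 3.18, 1.46 and 1.88 CPM. The oncofetal gene Afp gave 42, 46 and 60 UMIs and Gpc3, a surface proteoglycan of liver cancer, 12, 16 and 11. Unnamed clusters held 9.78% ± 1.16 of cells. Clusters with high doublet scores took 2.85% on average, and were kept out by a limit set after the data were seen, with 2.89%, 3.56% and 2.09% in libraries 1, 2 and 3. A cluster led by C1qa, C1qc, Vcam1 and Mertk took 3.52%. It was left unnamed because its leading genes are on the Kupffer list while its markers scored best for monocytes or macrophages, so the Kupffer-like share depends on this naming. Of the 46 Kupffer-like cells 28 were in library 1, and without that library the share was 0.0815%. A cluster led by plasma cell genes took 1.30% and clusters with under 3 markers 2.11%.

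As a share of UMIs, transcripts of the Y chromosome were abundant in the lymphocytes and lower in the myeloid antigen-presenting cells. The 4 measured genes lie on chromosome Y of GRCm38. Kdm5d (ENSMUSG00000056673), a histone demethylase, spans 897788 to 956786 on the plus strand. Eif2s3y (ENSMUSG00000069049), a translation initiation factor, spans 1010543 to 1028847 on the plus strand. Uty (ENSMUSG00000068457), a copy of the demethylase Kdm6a, spans 1096861 to 1245759, and Ddx3y (ENSMUSG00000069045), an RNA helicase, spans 1260771 to 1286629, both on the minus strand. Their sum was 415 ± 43.9 CPM in T-like cells (SD, n = 3), 405 ± 28.4 in NK or innate lymphoid-like cells and 394 ± 27.7 in B-like cells. It was 364 ± 17.97 in plasmacytoid dendritic-like cells and 417 ± 65.4 in neutrophil-like cells. Monocyte or macrophage-like cells had 249 ± 8.95, conventional dendritic-like cells 232 ± 25.8, basophil or mast-like cells 233 ± 31.9 and Kupffer-like cells 60.3 ± 20.5. The unnamed cluster led by C1qa had 255 ± 16.1 of the Y genes and 471 ± 37.9 of the X copies. Xist, the RNA of the inactive X chromosome, gave 3, 2 and 1 UMIs in libraries 1, 2 and 3. Ddx3x, Eif2s3x, Kdm5c and Kdm6a are X copies of the 4 genes, and Usp9x and Zfx are X copies of Y genes outside the sum. These 6 X copies summed to 494 ± 16.1 CPM in T-like and 463 ± 39.9 in monocyte or macrophage-like cells. They were also low where the Y genes were low in conventional dendritic-like (339 ± 33.5), basophil or mast-like (379 ± 35.95) and Kupffer-like cells (167 ± 82.0). They were 576 ± 39.8 in B-like, 500 ± 21.3 in NK or innate lymphoid-like, 496 ± 26.7 in plasmacytoid dendritic-like and 748 ± 112 in neutrophil-like cells, and these levels were not tested.

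**Figure D1:**
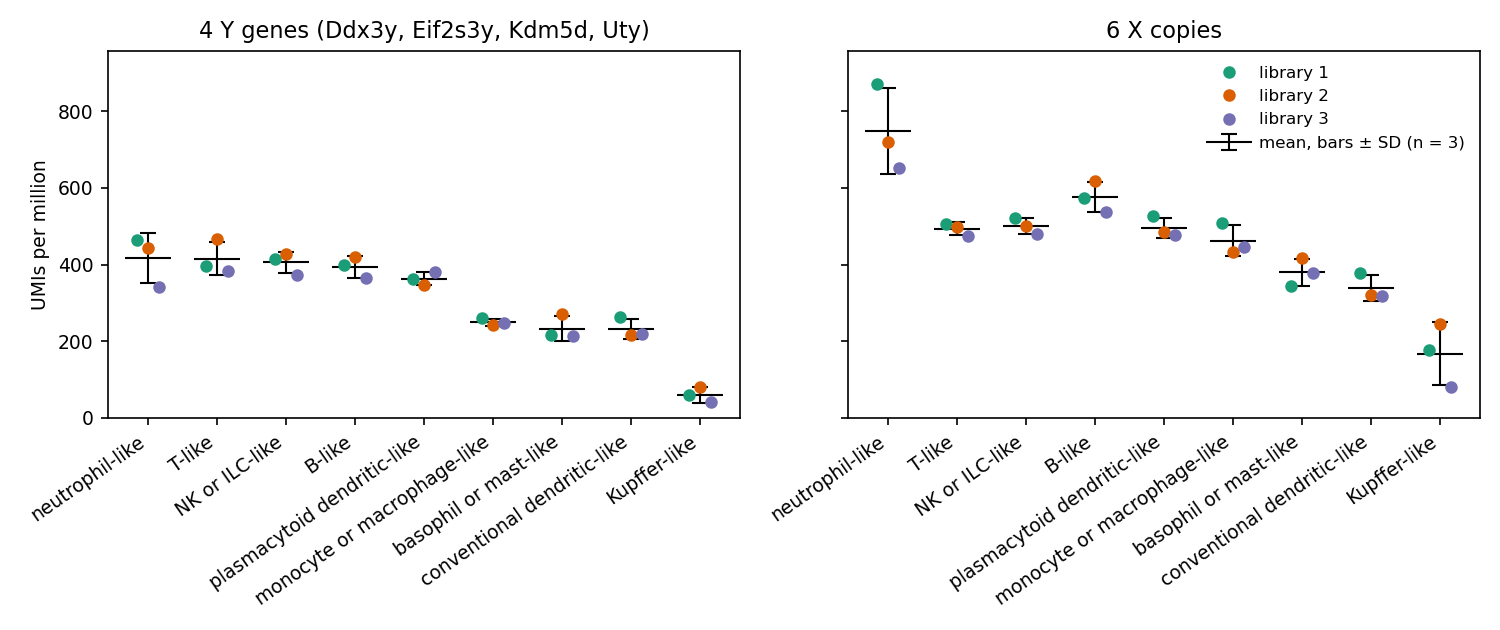
Level in CPM of the 4 Y genes (left) and of 6 X copies of Y genes (right) in each cell class, with a point per library and bars for the mean ± SD of 3 libraries. T-like cells lie at a mean of 415 for the Y genes and monocyte or macrophage-like cells at 249, while Kupffer-like cells lie lowest in both panels, at 60.3 and 167.

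Against T-like cells, the summed Y genes were lower in monocyte or macrophage-like cells by -0.48 ± 0.10 on the log2 scale (SE; edgeR adjusted p = 0.000182) and in conventional dendritic-like cells by -0.58 ± 0.10 (edgeR adjusted p = 2.81e-05). Basophil or mast-like cells were also lower, at -0.49 ± 0.13 (edgeR adjusted p = 0.00200). Uty carried most of this difference, at -1.02 in monocyte or macrophage-like and -1.06 in conventional dendritic-like cells, whereas Eif2s3y differed by 0.05 and -0.09, both short of the threshold. NK or innate lymphoid-like cells at -0.11 ± 0.10 (edgeR adjusted p = 0.318), B-like cells at -0.02 ± 0.10 (edgeR adjusted p = 0.817) and plasmacytoid dendritic-like cells at -0.20 ± 0.10 (edgeR adjusted p = 0.0901) did not pass. The plasmacytoid dendritic-like value depended on the settings. It was -0.34 without library 3 (edgeR adjusted p = 0.0371) and -0.0865 without library 2 (0.637). In B-like cells single genes went opposite ways, with Uty at -0.57 and Kdm5d at 0.44. Neutrophil-like cells were higher by 0.61 ± 0.11 (edgeR adjusted p = 2.81e-05), with Ddx3y at 1.07, Eif2s3y at 1.15 and Kdm5d at -2.18. That rise was 0.003 without normalization factors, and the levels in CPM of neutrophil-like and T-like cells were nearly equal. The fit covered 12494 genes.

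Within T-like cells, the clusters led by Il23r and by Il17a had the most Y transcripts. Each T cluster was compared with the unweighted mean of the other T clusters, so a small cluster counted as much as a large one. The cluster led by Abi3bp, Cd163l1 and Il23r, the receptor of interleukin 23, had 606 ± 46.1 CPM. It stood 0.45 ± 0.07 above the mean of the other clusters on the log2 scale (edgeR adjusted p = 2.37e-06). The cluster led by Il17a, Il17f and Il22 had 570 ± 23.9 and stood 0.41 ± 0.07 above the mean of the others (edgeR adjusted p = 1.48e-05). Uty was higher by 0.84 and 0.76 in these clusters and Ddx3y by 0.37 in both, while Eif2s3y was at -0.03 and 0.08. Lower sums were found in the Gzmk and Pdcd1 cluster (-0.22 ± 0.07, edgeR adjusted p = 0.00882), in the Gzmm cluster (-0.21 ± 0.07, edgeR adjusted p = 0.0123) and in the Gzma and Klra1 cluster (-0.23 ± 0.08, edgeR adjusted p = 0.0157). These 3 calls were the least firm. The first was lost without library 1 (edgeR adjusted p = 0.0683), the second without library 3 (0.193), and the third without any of the 3 libraries (0.0501 to 0.142). Without the library as a block all 3 were lost (edgeR adjusted p from 0.259 to 0.261). Without normalization factors the Gzma cluster, whose 415 ± 64.5 CPM matched the mean of T-like cells, stood at -0.0581 (0.480), and the Igfbp4 cluster turned to -0.27 and was called (0.00181). The regulatory cluster stood at -0.003 ± 0.07, the Il4 and Zbtb16 cluster at -0.12 ± 0.07, the Igfbp4 and Dapl1 cluster at 0.07 ± 0.07 and the Ifit3 cluster at -0.15 ± 0.10, with edgeR adjusted p from 0.167 to 0.963. The fit covered 9744 genes.

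**Figure D2:**
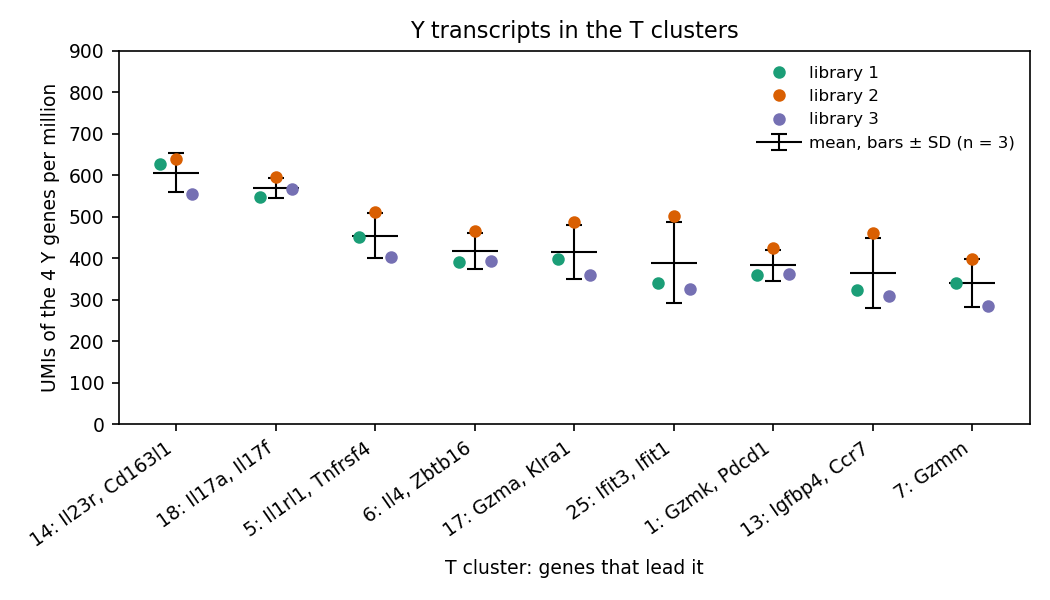
Level of the 4 Y genes in CPM in the 9 T clusters, each named by its number and genes that lead it, with a point per library and bars for the mean ± SD of 3 libraries. The clusters led by Il23r and Il17a lie highest, at means of 606 and 570.

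Many cells had 0 UMIs of the 4 Y genes, and most of that share was what counting gives at this depth. At full depth, the share was 30.2% ± 2.28 of T-like cells (SD, n = 3; median 3460.5 UMIs), 39.9% ± 2.16 of B-like (2604) and 26.4% ± 4.005 of NK or innate lymphoid-like cells (3765). It was 25.9% ± 3.37 of monocyte or macrophage-like (6584.5), 23.7% ± 3.17 of conventional dendritic-like (8234), 14.5% ± 6.49 of plasmacytoid dendritic-like (6320.5) and 49.2% ± 3.03 of neutrophil-like cells (2269). The monocyte or macrophage-like and conventional dendritic-like cells, lower in Y CPM but deeper, thus held no larger share without Y UMIs than T-like cells. No class of these libraries should lack Y genes, so a background share from free RNA could not be measured, and Alb stood at 0.2 CPM in T-like cells. With each cell thinned to 2000 UMIs, 48.3% ± 2.54 of T-like cells had none against a Poisson share of 43.7%, an excess of 4.59 ± 0.909 percentage points. Thinning left out 101, 366 and 485 shallower T-like cells in libraries 1, 2 and 3.

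The excess of T-like cells lay at percentile 91.2 of 1000 matched autosomal sets, whose median was 2.02 and whose 5th and 95th percentiles were 0.356 and 5.54. Neutrophil-like cells had an excess of 9.52 ± 4.08 points, at percentile 93.4, with a median of 4.22 in matched sets. The excess was 2.76 ± 1.27 in NK or innate lymphoid-like, 2.87 ± 1.34 in B-like, 2.13 ± 0.902 in monocyte or macrophage-like, 3.12 ± 0.368 in conventional dendritic-like and 2.47 ± 2.21 in plasmacytoid dendritic-like cells, at percentiles 81.5 to 88.5. No class passed, with an adjusted rank p of 0.186 in all 7. The Y genes were also removed from a random share of cells, with 1 draw per share, on top of the excess already present. The resulting p-values therefore do not give the power to detect a loss of that size. With the Y genes removed at random from 20% of cells, the unadjusted rank p was still 0.0669 in monocyte or macrophage-like and 0.125 in conventional dendritic-like cells, but 0.0250 in NK or innate lymphoid-like and 0.0140 in plasmacytoid dendritic-like cells. From 10% of cells it was 0.0320 in T-like and 0.0220 in B-like cells, and from 5% it was 0.0529 and 0.0679 there. With no removal the unadjusted rank p was 0.0889 in T-like and 0.116 in B-like cells. In neutrophil-like cells it was 0.0669 with no removal, 0.0430 from 5% and 0.04995 from 10%, so a loss of 5% is not shown to be detectable there. Among cells deep enough to expect at least 5 Y UMIs, 1 of 104 T-like cells had none (0.312 expected, exact upper limit 5.24%), as did 1 of 108 monocyte or macrophage-like cells (0.308 expected, upper limit 5.05%) and 1 of 39 conventional dendritic-like cells (0.139 expected, upper limit 13.5%). The share was 0 of 43 NK or innate lymphoid-like cells, with an exact upper limit of 8.22%. It was 0 of 15 B-like, 0 of 20 plasmacytoid dendritic-like and 0 of 3 neutrophil-like cells, with upper limits of 21.8%, 16.8% and 70.8%.

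The Y genes were nevertheless found together in a cell more often than depth alone gives. Over 6 pairs of Y genes, the odds ratio of joint detection was 1.17 in T-like cells (1.18, 1.18 and 1.16 in libraries 1, 2 and 3) and 1.17 in monocyte or macrophage-like cells (1.15, 1.18 and 1.16). It was 1.48 in conventional dendritic-like cells (1.74, 1.38 and 1.35) and 2.08 in neutrophil-like cells (2.82, 2.10 and 1.52). The matched autosomal sets had medians of 1.04, 1.04, 1.04 and 1.24 in these 4 classes, and 95th percentiles of 1.13, 1.13, 1.22 and 1.70. Each matched set held genes on different chromosomes, whereas the Y genes lie near one another, so the comparison does not account for position. Ranks among the 200 sets gave adjusted p = 0.0373 for T-like and for monocyte or macrophage-like cells, and 0.0299 for conventional dendritic-like and for neutrophil-like cells. B-like cells at 1.12 (rank among the sets, adjusted p = 0.113) and NK or innate lymphoid-like cells at 1.08 (adjusted p = 0.289) did not pass. Without library 1 the call was lost in all 4 classes (rank among the sets, adjusted p = 0.0796, 0.0796, 0.0597 and 0.104), and it was also lost without library 2 in T-like cells (0.0522) and without library 2 or 3 in monocyte or macrophage-like cells (0.0657 and 0.0746). When the Y genes were removed from 2%, 5%, 10% and 20% of T-like cells at random, the odds ratio rose from 1.17 to 1.22, 1.31, 1.45 and 1.91.

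**Figure D3:**
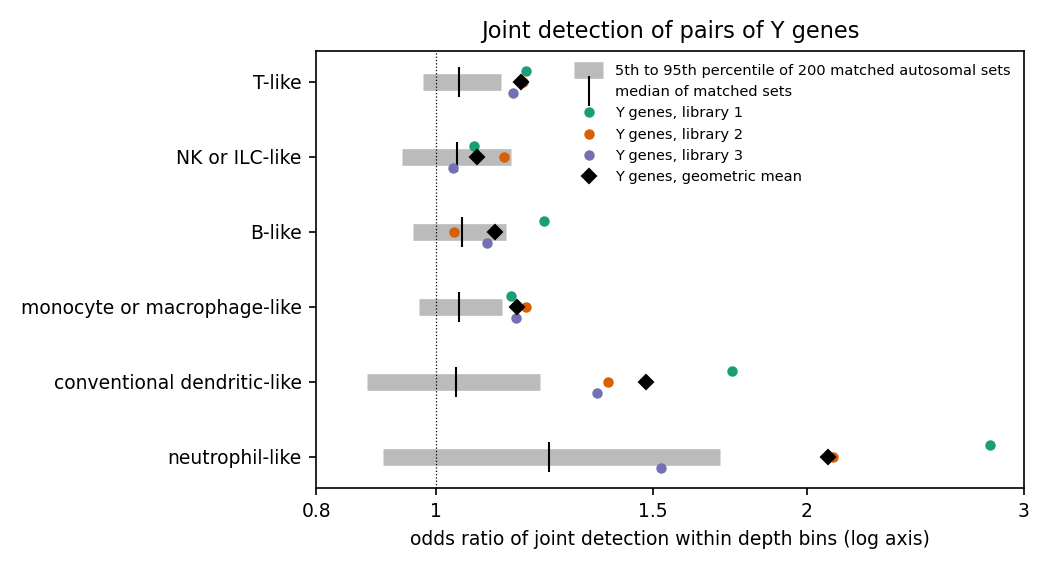
Odds ratio (log axis) that a pair of Y genes is detected in the same cell within depth bins, for each class, with a point per library and a diamond for the geometric mean; grey bars span the 5th to 95th percentile of 200 matched autosomal sets and ticks their median. The diamonds of T-like (1.17), monocyte or macrophage-like (1.17), conventional dendritic-like (1.48) and neutrophil-like cells (2.08) lie beyond the grey bars.

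T-like cells without Y UMIs had fewer transcripts of Il17a, Il17re and Il23r and more of Gzmm than T-like cells of the same depth with Y UMIs. None of these 4 was called once cells were also matched on cluster. The Il23r and Il17a clusters had the most Y transcripts and the Gzmm cluster a lower sum. A split by Y UMIs therefore tends to place their cells unequally, so these shifts partly restate the Y levels of the clusters. Among 3016 cells of each status (median 2923 and 2946 UMIs), 180 genes were higher and 205 lower of 9933 tested with edgeR at adjusted p under 0.05, and 376 of the 385 kept 1 direction in all libraries. The cytokine gene Il17a fell by 0.85 ± 0.06 on the log2 scale, from 300 to 155 CPM (edgeR adjusted p = 7.56e-28; -1.34, -0.15 and -1.07 in libraries 1, 2 and 3). Il23r fell by 0.93 ± 0.12 (edgeR adjusted p = 5.10e-11) and Il17re, an interleukin 17 receptor subunit, by 0.84 ± 0.25 (edgeR adjusted p = 0.0278). Gzmm, a granzyme, rose by 1.11 ± 0.20 (edgeR adjusted p = 1.17e-05), with 1.75, 0.37 and 1.05 in the 3 libraries.

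The largest other falls in T-like cells were Ikbip at -1.35 ± 0.43, Plekhg1 at -1.19 ± 0.22, 4930430F08Rik at -1.02 ± 0.29, Gm20732 at -0.90 ± 0.24. They also held Ttn, the giant protein of muscle, at -0.88 ± 0.26, Olfr60 at -0.87 ± 0.23 and Cysltr1, a leukotriene receptor, at -0.86 ± 0.27 (edgeR adjusted p from 2.35e-05 to 0.0468). The largest other rises were Atat1, a tubulin acetyltransferase, at 1.46 ± 0.42, Coch at 0.76 ± 0.21, Gm49313 at 0.73 ± 0.18. Smaller ones were Znhit2 at 0.70 ± 0.21, Gm11361 at 0.61 ± 0.16, Txndc5 at 0.55 ± 0.14, Igfbp4 at 0.51 ± 0.13, Csrp1 at 0.48 ± 0.13 and Trmt10c, a mitochondrial transfer RNA methyltransferase, at 0.47 ± 0.15 (edgeR adjusted p from 0.00363 to 0.0468). The X copies stood between -0.13 (Ddx3x) and 0.04 (Kdm5c) and none passed, the smallest edgeR adjusted p being 0.425.

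**Figure D4:**
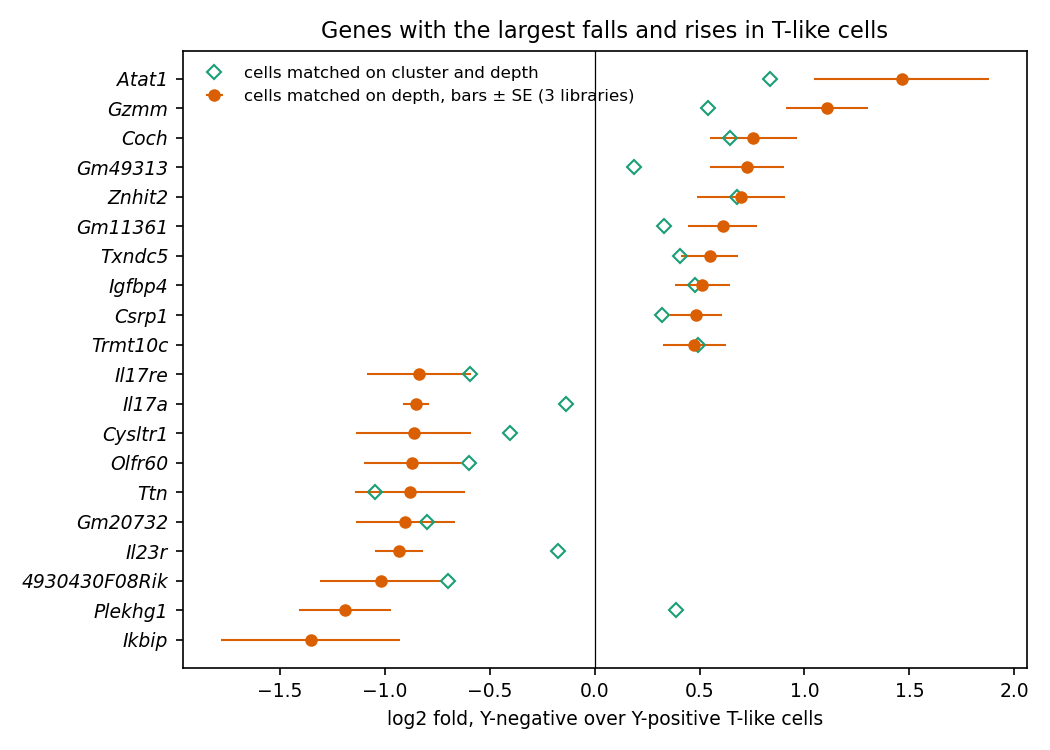
Log2 fold of Y-negative over Y-positive T-like cells for the 10 largest falls and the 10 largest rises; circles with bars are the fold ± SE over 3 libraries with cells matched on depth, and diamonds the fold with cells matched on cluster and depth. Il17a stands at -0.85 and -0.13 and Plekhg1 at -1.19 and 0.39.

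No list call in T-like cells held with an estimated correlation (adjusted p = 0.423 or higher with an estimated correlation). Among the lists of T cell states, the gamma-delta T cell markers fell, with 3 of 6 members down (adjusted over the list alone 4 down and 1 up), a median of -0.25 and a camera adjusted p of 0.00235. Il23r and Trdc, the delta chain of the receptor, at -0.26 were among those members. The CD4 markers had 2 of 5 down (adjusted over the list alone also 2), with the costimulator Icos at -0.39 and Cd40lg at -0.22 (median -0.14, camera adjusted p = 0.000635). Tissue residency had 2 of 8 down (adjusted over the list alone 2), the integrin gene Itgae at -0.52 and Crem at -0.22 (median -0.07, camera adjusted p = 0.0398). The CD8 markers had 3 of 6 up (adjusted over the list alone 4), with Cd8b1 at 0.39, the chemokine gene Ccl5 at 0.25 and Ctsw at 0.20 (median 0.17, camera adjusted p = 2.05e-08). The cytotoxic list had 2 of 13 up (adjusted over the list alone 2), Nkg7 at 0.28 and Ccl5 (median 0.03, camera adjusted p = 0.00264). With cells matched on cluster, the gamma-delta median turned to 0.0794 (camera adjusted p = 0.251), and the calls of the CD4 markers (median -0.0766, 0.336) and of tissue residency (-0.0367, 0.352) were lost. Without depth matching the CD4 median turned to 0.0347.

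Ribosomal protein genes rose almost throughout in Y-negative T-like cells. Of 82 tested, 75 were higher (adjusted over the list alone 78), with Rpsa, Rpl15 and Rpl6 at 0.23 each and Rpl28 at 0.22 (median 0.18, camera adjusted p = 1.93e-131, adjusted p = 0.423 with an estimated correlation). Splits of the same cells by matched autosomal genes gave a ribosomal median at least as high in 4 of 20. Mitochondrial transcripts had 1 of 13 up, mt-Atp6 at 0.12 (adjusted over the list alone 4; median 0.08, camera adjusted p = 0.000476), T cell markers 2 of 8 up, Cd3d at 0.19 and Trbc2 at 0.14 (adjusted over the list alone 2; median 0.05, camera adjusted p = 0.00320), and MHC class I 0 of 9 (adjusted over the list alone 3 up; median 0.08, camera adjusted p = 0.00235). The share of cells with a UMI of the 8 T cell markers was 99.9% in Y-negative and 99.6% in Y-positive T-like cells.

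Exhaustion genes did not move as a group in T-like cells. Pdcd1 rose by 0.29 (edgeR adjusted p = 0.0374) and the nuclear receptor gene Nr4a2 fell by 0.18, the only calls among 12 members (adjusted over the list alone 1 up and 2 down; median -0.07, camera adjusted p = 0.447). The naive or memory list had 2 of 10 up, among them Klf2 at 0.13 (adjusted over the list alone 3 up and 1 down; median 0.05, camera adjusted p = 0.222). The regulatory T list had 3 of 10 down, Il2ra at -0.39, Icos and Ikzf2 at -0.17 (adjusted over the list alone 1 up and 4 down; camera adjusted p = 0.229), and its median of 0.14 had the opposite sign to its test. Interferon response had 1 of 12 up, Ifi27l2a at 0.14 (adjusted over the list alone 1; camera adjusted p = 0.242), and DNA damage and p53 had 1 of 8 down, Gadd45b at -0.21 (adjusted over the list alone 1; median -0.12, camera adjusted p = 0.242).

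Naive or central memory markers had a camera adjusted p of 0.242 (adjusted over the list alone 2 up and 1 down). Apart from that list, no member of the remaining lists passed over all genes in T-like cells except Ly6c2 at 0.30 and the chemokine receptor gene Ccr2 at -0.38 among 4 monocyte or macrophage markers (adjusted over the list alone 1 up and 1 down; camera adjusted p = 0.822), and Il2ra and Ikzf2 among 6 regulatory markers (adjusted over the list alone 2 down; 0.479). The other camera adjusted p-values in T-like cells were 0.0678 for stress (adjusted over the list alone 2 down), 0.172 for MHC class II, 0.885 for the cell cycle, 0.423 for the X copies, 0.632 for liver tumour genes, and 0.571 for lipid handling. They were 0.981 for the cycling state, 0.924 for NK or innate lymphoid markers, 0.885 for B markers, 0.822 for neutrophil markers and 0.632 for plasmacytoid dendritic markers. In these 10 lists apart from stress, the counts adjusted over the list alone were also 0. The median and the test had opposite signs for liver tumour genes (0.04), the cycling state (0.02), neutrophil markers (0.15), NK or innate lymphoid markers (-0.03) and regulatory markers (0.01). Liver secreted genes and the markers of hepatocytes, cholangiocytes, endothelial, stellate, plasma, Kupffer, conventional dendritic, basophil, erythroid and platelet cells had under 3 members tested.

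Part of the T-like difference was a difference in cluster makeup. The Il23r cluster held 5.24% ± 2.23 of Y-negative and 7.89% ± 2.80 of Y-positive cells (SD, n = 3), lower in 3 of 3 libraries, and the Il17a cluster 3.31% ± 2.34 and 4.75% ± 3.22, lower in 2 of 3. With cells matched on cluster as well as depth, chosen after the data were seen, edgeR called 263 genes, 184 of them among the 385. Il17a then stood at -0.13 (edgeR adjusted p = 0.341), Il23r at -0.18 (0.667), Il17re at -0.59 (0.298), Pdcd1 at 0.12 (0.607) and Gzmm at 0.54 (0.0770), while Ttn at -1.05, Gm20732 at -0.80, Znhit2 at 0.68, Trmt10c at 0.49 and Igfbp4 at 0.48 still passed. The 20 splits by matched autosomal genes called 11 to 941 genes (median 174), and 5 of them called at least 385. DESeq2 called 157 genes, 126 higher and 31 lower, edgeR without library 2 called 151 and without library 3 called 169. Without the library as a block, edgeR called 0, with 269 at unadjusted p under 0.05.

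**Figure D5:**
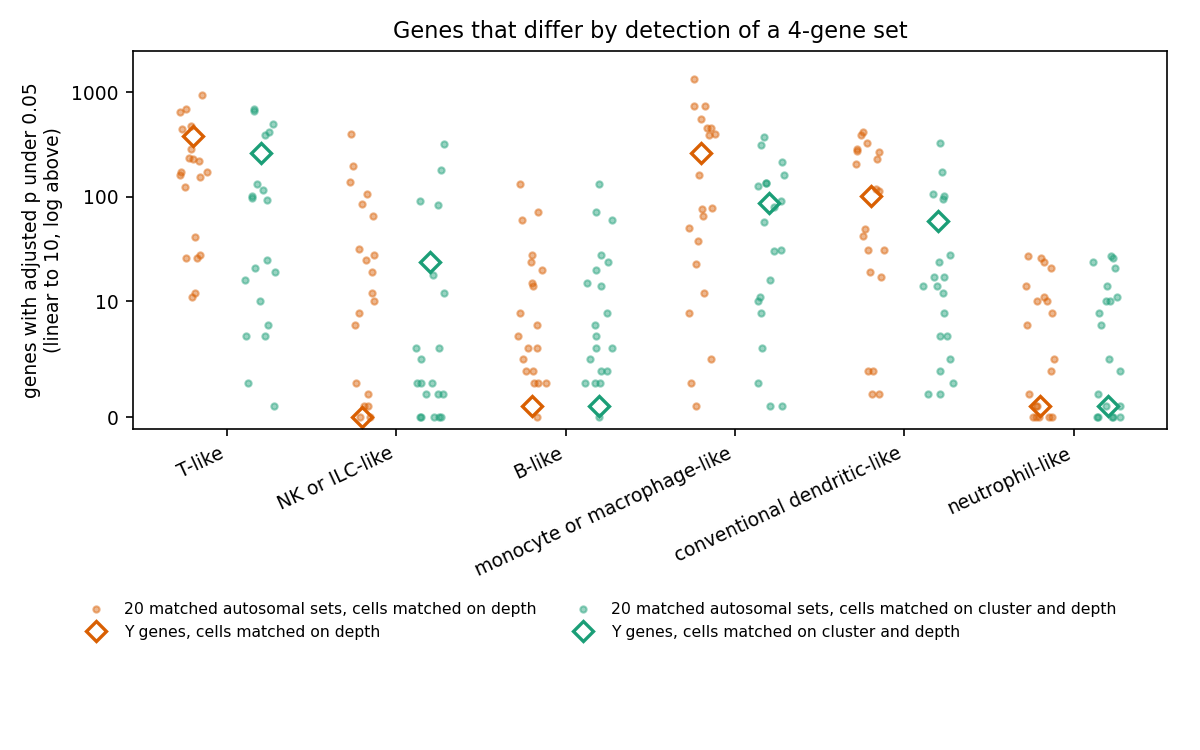
Number of genes with edgeR adjusted p under 0.05 between cells with and without UMIs of a 4-gene set (linear to 10, log above), with diamonds for the Y genes and points for 20 matched autosomal sets, in each class and for both ways of matching cells. In T-like cells the Y genes give 385 and 263 genes, inside the range of 11 to 941 and of 1 to 695 from the autosomal sets.

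Monocyte or macrophage-like cells without Y UMIs had more transcripts of 4 MHC class II genes, of C1qa and C1qb and of 4 stress genes. Among 1282 cells of each status (median 5809 and 5825.5 UMIs), 122 genes were higher and 142 lower of 9003 tested, and 243 kept 1 direction in all libraries. No list call in this class held with an estimated correlation (adjusted p = 0.396 or higher with an estimated correlation). The class II gene H2-Eb1 rose by 0.31 ± 0.04 (edgeR adjusted p = 1.12e-08), H2-Ab1 by 0.28, H2-Aa by 0.26 and their chaperone Cd74 by 0.26, the 4 calls among 7 class II genes (adjusted over the list alone 5; median 0.26, camera adjusted p = 3.31e-09). Of 12 stress genes, 4 were higher, among them the heat shock genes Hspa1a at 0.32 and Hspa1b at 0.28, the immediate early gene Egr1 at 0.84 and Jun at 0.30 (adjusted over the list alone 6 up and 1 down; median 0.13, camera adjusted p = 3.14e-06), and this list call was lost with cells matched on cluster (median 0.11, 0.141), where the median was nearly as high. The complement genes C1qb and C1qa rose by 0.45 and 0.33.

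Lipid genes of monocyte or macrophage-like cells went both ways. Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 1.32 ± 0.30 (edgeR adjusted p = 0.00201) and Fabp5, a fatty acid binding protein, by 0.35, while Fabp4 fell by 0.40 and the fatty acid receptor Cd36 by 0.32. These were the 4 calls among 10 lipid handling genes (adjusted over the list alone 2 up and 2 down; median -0.02, against a test that pointed up, camera adjusted p = 0.666). Other large rises were the chemokine gene Ccl12 at 1.25 ± 0.33, Tmem140 at 1.23 ± 0.37, Kazn at 1.18 ± 0.26. Smaller ones were Acadvl, a fatty acid oxidation enzyme, at 0.76 ± 0.17, Il1rn, the interleukin 1 receptor antagonist, at 0.58 ± 0.11, Nr1h3, the sterol sensor LXR alpha, at 0.57 ± 0.15, Maz at 0.56 ± 0.17, the metallothionein Mt1 at 0.55 ± 0.11 and Ccdc86 at 0.53 ± 0.16 (edgeR adjusted p from 0.000212 to 0.0476). The largest falls were Gm2682 at -1.64 ± 0.37, Kctd9 at -1.26 ± 0.31, Erich1 at -0.86 ± 0.24, Afg1l at -0.82 ± 0.25. Next came Lmbrd2 at -0.80 ± 0.20, Cnnm2 at -0.73 ± 0.18, Tiam2 at -0.71 ± 0.15, Sfi1 at -0.68 ± 0.19, the ion transporter Slc12a2 at -0.54 ± 0.15 and Setbp1 at -0.54 ± 0.15 (edgeR adjusted p from 0.000516 to 0.0385). Without depth matching, Slc12a2 turned to 0.32 and Setbp1 to 0.21. None of the 10 largest rises and 10 largest falls passed with cells matched on cluster (smallest edgeR adjusted p = 0.0802, for Mt1), though many folds stayed nearly as large. Lmbrd2 stood at -0.72, Erich1 at -0.73, Afg1l at -0.69, Maz at 0.44 and Acadvl at 0.57, while Slc12a2 at -0.02, Il1rn at 0.18 and Gpnmb at 0.20 shrank most in proportion to their log2 fold. The X copies stood between -0.16 and 0.12 with a smallest edgeR adjusted p of 0.325.

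Further lists moved up in monocyte or macrophage-like cells, each lost with an estimated correlation (adjusted p = 0.396 to 0.402 with an estimated correlation). Ribosomal proteins had 24 of 83 up (adjusted over the list alone 64; camera adjusted p = 8.42e-25), their own markers 3 of 11, Gpnmb, Lyz2 at 0.15 and Ly6c2 at 0.23 (adjusted over the list alone 4; 0.00228), interferon response 2 of 12, Isg15 at 0.25 and Ifi27l2a at 0.17 (adjusted over the list alone 2; 0.00797). Cytotoxic effector had 1 of 6, the chemokine gene Ccl4 at 0.28 (adjusted over the list alone 2; 0.0491), MHC class I 0 of 9 (adjusted over the list alone 1; 0.0491) and liver tumour genes 0 of 7 (adjusted over the list alone 1; 0.0491). Matching on cluster ended the calls of interferon response (median 0.0480, camera adjusted p = 0.683), cytotoxic effector (0.17, 0.0552), MHC class I (0.0592, 0.181), plasmacytoid dendritic markers (-0.13, 0.181) and liver tumour genes, whose median turned to -0.0231 (0.835). Without depth matching the cytotoxic median turned to -0.33 and the liver tumour median to -0.0512. Of the plasmacytoid dendritic markers 1 of 3 was lower, the transcription factor Runx2 at -0.41 (adjusted over the list alone 2; camera adjusted p = 0.0491). With cells matched on cluster, 88 genes passed, 75 of them among the 264, with C1qa at 0.58, H2-Eb1 at 0.27, Gpnmb at 0.20, Cd36 at -0.11 and Fabp4 at 0.00. Matched autosomal sets called 1 to 1356 genes, at least 264 in 8 of 20, and gave a class II median as high in 11 of 20. DESeq2 called 32 genes, edgeR without library 2 called 50, and edgeR without the library as a block called 0, with 156 at unadjusted p under 0.05.

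Conventional dendritic-like cells without Y UMIs had fewer transcripts of the lymphocyte genes Skap1, Gimap6 and Ets1 and more of Lyz2, Hspa1a and Hspa1b. Among 516 cells of each status (median 7209 and 7174 UMIs), 17 genes were higher and 84 lower of 7343 tested, all 101 in 1 direction in all libraries. The largest falls held Skap1, an adaptor of T cell receptor signalling, at -1.21 ± 0.25, the lymphocyte gene Gimap6 at -1.50 ± 0.32 and the transcription factor Ets1 at -1.33 ± 0.27. They also held Ly6d at -2.45 ± 0.38, Mir99ahg at -1.91 ± 0.40, Ppp1r16b at -1.33 ± 0.30, Adam23 at -1.31 ± 0.17, Apol7c at -1.28 ± 0.23 and Pecam1 at -1.20 ± 0.28 (edgeR adjusted p from 0.000941 to 0.0328). T cell markers had 0 of 5 members past the threshold over all genes (adjusted over the list alone 3 down; median -1.10, camera adjusted p = 0.00284, adjusted p = 0.552 with an estimated correlation). Skap1 (-1.05, edgeR adjusted p = 0.0843), Gimap6 (-1.01, 0.249) and Ets1 (-0.91, 0.202) were no longer called with cells matched on cluster. Cells with a UMI of a T cell marker were 7.39% ± 1.02 of Y-negative and 9.58% ± 2.48 of Y-positive dendritic-like cells (SD, n = 3), lower in 2 of 3 libraries.

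The rises in conventional dendritic-like cells held the haptoglobin gene Hp at 1.40 ± 0.33, the chemokines Cxcl10 at 1.04 ± 0.21 and Ccl17 at 0.94 ± 0.22, lysozyme Lyz2 at 0.77 ± 0.12. They also held Fkbp1a at 0.58 ± 0.12, the heat shock genes Hspa1a at 0.57 ± 0.09 and Hspa1b at 0.47 ± 0.09, thioredoxin Txn1 at 0.46 ± 0.08, Sdf2l1 at 0.44 ± 0.10 and the respiratory chain gene Uqcrb at 0.38 ± 0.09 (edgeR adjusted p from 0.00175 to 0.0328). In cells without UMIs of the T cell markers Cxcl10 turned to -0.63 and Ccl17 to -0.52. Without depth matching Cxcl10 turned to -0.10 and Hp to -0.14, and Hp was at -0.0540 at resolution 2. Of these 10 rises only Lyz2 was called with cells matched on cluster (0.57, edgeR adjusted p = 0.00202), though Hspa1b at 0.43, Ccl17 at 0.81, Cxcl10 at 0.76 and Txn1 at 0.35 stayed nearly as high and Hp fell to 0.39. Interferon response had 0 of 12 members past the threshold over all genes (adjusted over the list alone 4 up; median 0.41, camera adjusted p = 6.47e-05), and 0 of 20 matched autosomal splits gave a median as high, the highest being 0.34. MHC class II had 0 of 7 (adjusted over the list alone 5 up; median 0.20, camera adjusted p = 0.00328), the naive or memory list 2 of 7 down, Bach2 at -0.44 and Satb1 at -0.78 (adjusted over the list alone 4; camera adjusted p = 0.00328, lost with cells matched on cluster at a median of -0.11 and 0.165), monocyte or macrophage markers 1 of 7 up, Lyz2 (adjusted over the list alone 1; 0.0262), and ribosomal proteins 0 of 82 (adjusted over the list alone 0; median 0.15, 1.97e-17). With an estimated correlation no list call held in this class (adjusted p = 0.552 or higher with an estimated correlation). With cells matched on cluster 59 genes passed, 35 of them among the 101, and matched autosomal sets called at least 101 in 10 of 20. DESeq2 called 22 genes, edgeR called 64 without library 1 and 44 without library 2, and edgeR without the library as a block called 0, with 325 at unadjusted p under 0.05.

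In the other classes the number of genes that differed between Y-negative and Y-positive cells depended on the settings. In NK or innate lymphoid-like cells, with 791 cells of each status, edgeR called 0 of 7268 genes, with 632 at unadjusted p under 0.05 and 0 by DESeq2, and the lowest adjusted p was 0.0555 for Malat1, named after its value was seen. With edgeR 36 passed without library 1, 25 without library 2, 32 with doublets kept, 24 with cells matched on cluster and 316 without depth matching. In B-like cells, with 1574 of each, edgeR called 1 of 7549, the chemokine gene Ccl5 at -1.56 (edgeR adjusted p = 1.98e-09), also named after its value was seen, with 10 calls without library 1, 2 without library 2 or 3, and 120 without depth matching. Ccl5 did not keep its direction in library 2, its call was lost without library 1 (-0.77, edgeR adjusted p = 0.150), at 10% mitochondrial UMIs (-0.63, 0.287) and by DESeq2 (-1.43), and it turned to 0.39 (0.834) with doublets kept. It stood at 0.43 (edgeR adjusted p = 0.784) in B-like cells without UMIs of the T cell markers. Such UMIs were in 1.84% ± 0.0728 of Y-negative and 3.81% ± 1.13 of Y-positive B-like cells (SD, n = 3). In neutrophil-like cells, with 361 of each, edgeR called 1 of 3124, Prok2, a chemoattractant, at 3.07 ± 0.55 (edgeR adjusted p = 0.0372), with 0 calls by DESeq2 (14 at unadjusted p under 0.05), 3 by edgeR without library 1 and 0 by edgeR without library 2 or without library 3 (120 and 129 at unadjusted p under 0.05).

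In these 3 classes camera called lists of which none held with an estimated correlation (adjusted p = 0.471, 0.539 and 0.808 or higher with an estimated correlation). In NK or innate lymphoid-like cells, camera called 7 lists, among them cytotoxic effector with a median of 0.14 (adjusted over the list alone 6 up and 1 down; camera adjusted p = 0.000428), naive or central memory markers with -0.25 (adjusted over the list alone 2 down; 0.00332) and interferon response with -0.18 (adjusted over the list alone 2 down; 0.0377). In B-like cells it called 7, among them interferon response with 0.17 (adjusted over the list alone 1 up; 0.00976) and the X copies with -0.15 (adjusted over the list alone 1 down; 0.0498). In neutrophil-like cells it called 5, among them MHC class II with 0.70 over 3 members (adjusted over the list alone 2 up; 0.000428) and mitochondrial transcripts with -0.22 (adjusted over the list alone 0; 0.00388). The MHC class II median turned to -0.44 without depth matching (camera adjusted p = 0.00883) and to -1.49 at 10% mitochondrial UMIs (4.21e-13), each called in the opposite direction. It was -0.11 with doublets kept and -0.17 without T cell marker UMIs, and the mitochondrial median was 0.0137 without library 3. The X copies did not pass as single genes, with smallest edgeR adjusted p-values of 0.565 in NK or innate lymphoid-like, 0.512 in B-like, 0.955 in neutrophil-like and 0.1204 in conventional dendritic-like cells.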

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

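Matching on cluster and depth, depth bins inside clusters, leaving out cells with UMIs of the T cell markers, and tests inside single T clusters were chosen after the results were seen. The other alternatives were planned. The excess of cells without Y UMIs stayed positive and short of the threshold in all 61 recalculations, with 2.29 to 6.60 points in T-like cells, in a test that simulated losses of 20% did not pass in monocyte or macrophage-like and conventional dendritic-like cells. Of the class differences in Y genes, 75 of 84 recalculations kept direction and call, as did 65 of 81 for the T clusters, 39 of 50 for joint detection and 30 of 96 for numbers of differing genes. Named genes kept direction and call in 357 of 801, lost the call in 436 and turned in 8. Lists kept both in 379 of 555, lost the call in 160 and turned in 16. X copies stayed as reported in 80 of 84 recalculations. Class shares moved by less than the SD between libraries in 59 of 60, the unnamed share being 17.7% with doublets kept, but the Kupffer-like share was 0.0815% without library 1 against 0.178%. An expected Y count of 3 left enough cells in T-like and monocyte or macrophage-like cells alone. Depth limits the status of single cells, since counting alone leaves 43.7% of T-like cells without Y UMIs at 2000 UMIs. Thinning to 4000 UMIs left too few B-like and neutrophil-like cells, joint detection with 2000 UMIs too few neutrophil-like cells, and DESeq2 gives no list tests. Filters, doublets and resolution were not varied for the T clusters, whose numbering changes with them. Unless stated, the cause was not tested.

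The lower Y levels of monocyte or macrophage-like, conventional dendritic-like and basophil or mast-like cells, as a share of UMIs, passed under every alternative run for them. So did the rises in the Il23r and Il17a clusters. Without normalization factors neutrophil-like cells stood at 0.00274, the Igfbp4 cluster at -0.27, called in the opposite direction, the Gzma cluster at -0.0581 and the regulatory cluster at 0.0912. The regulatory cluster, at -0.003 as reported, also turned to 0.00876 without a filter and to 0.0432 with the pair of highest Y genes. Plasmacytoid dendritic-like cells passed at -0.31 without a filter, -0.21 with DESeq2, -0.34 with the pair of highest Y genes, -0.24 with doublets kept, -0.26 at 10% mitochondrial UMIs, -0.28 at resolution 2 and -0.34 without library 3. Leaving out each library gave -0.34 to -0.0865 there, -0.0722 to 0.0591 in B-like cells, and -0.25 to -0.19 in the Gzmk and Pdcd1 cluster. It gave -0.0248 to 0.0225 in the regulatory cluster, -0.25 to -0.16 in the Gzmm cluster, -0.0384 to 0.12 in the Igfbp4 cluster and -0.24 to -0.21 in the Gzma cluster. Joint detection lost its call with doublets kept in T-like (1.17) and monocyte or macrophage-like cells (1.14), and in the latter with 2000 UMIs (1.16) and at resolution 2 (1.16). Without each library the odds ratio was 1.17 to 1.18 in T-like, 1.16 to 1.17 in monocyte or macrophage-like, 1.37 to 1.55 in conventional dendritic-like and 1.79 to 2.43 in neutrophil-like cells, with fewer samples each time.

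Without the library as a block, edgeR called 0 genes by Y status in all 6 classes, with 269 in T-like, 242 in NK or innate lymphoid-like, 117 in B-like, 156 in monocyte or macrophage-like, 325 in conventional dendritic-like and 37 in neutrophil-like cells at unadjusted p under 0.05. DESeq2 with the block called 157, 0, 0, 32, 22 and 0 in the same order. The unpaired fit also moved the Gzmk and Pdcd1 cluster to -0.23, the Gzma cluster to -0.21 and the Gzmm cluster to -0.20, all short of the threshold, and the regulatory cluster to 0.00115. The pairing changed no other call on Y genes.

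Numbers of differing genes moved most. Without depth matching they were 694 in T-like, 316 in NK or innate lymphoid-like, 120 in B-like, 349 in conventional dendritic-like and 7 in neutrophil-like cells. With Y-positive at 2 UMIs they were 721, 19, 77, 490 and 0 (110 at unadjusted p under 0.05) in the same classes and 685 in monocyte or macrophage-like cells. An expected Y count of 3 gave 58 in T-like and 24 in monocyte or macrophage-like cells, with 1574 genes tested in T-like cells. With no filter the numbers were 170 in T-like, 39 in NK or innate lymphoid-like, 20 in B-like, 116 in monocyte or macrophage-like, 209 in conventional dendritic-like and 14 in neutrophil-like cells. DESeq2 size factors gave 1 in NK or innate lymphoid-like and 0 in neutrophil-like cells (138 at unadjusted p under 0.05). Doublets kept gave 0 in B-like (510 at unadjusted p under 0.05), 32 in NK or innate lymphoid-like and 316 in conventional dendritic-like cells. A limit of 10% mitochondrial UMIs gave 5 in B-like and 302 in conventional dendritic-like cells. Resolution 2 gave 4 in B-like, 12 in NK or innate lymphoid-like and 58 in monocyte or macrophage-like cells. Matching on cluster gave 24 in NK or innate lymphoid-like, 88 in monocyte or macrophage-like and 59 in conventional dendritic-like cells. Cells without T cell marker UMIs gave 2 in B-like and 0 in neutrophil-like cells (155 at unadjusted p under 0.05). Without each library the ranges were 151 to 312 in T-like, 0 to 36 in NK or innate lymphoid-like and 2 to 10 in B-like cells. They were 50 to 251 in monocyte or macrophage-like, 44 to 74 in conventional dendritic-like and 0 to 3 in neutrophil-like cells. Inside single T clusters, edgeR called 114 genes in the Gzmk and Pdcd1 cluster (1 to 119 without each library), 7 in the regulatory cluster (0 to 21), 70 in the Il4 cluster (15 to 67) and 15 in the Gzmm cluster (1 to 27).

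Directions that turned were Plekhg1 in T-like cells at 0.39 with cluster matching, and Cxcl10 and Ccl17 in conventional dendritic-like cells at -0.63 and -0.52 without T cell marker UMIs. Ccl5 in B-like cells turned to 0.39 with doublets kept and 0.43 without T cell marker UMIs. Without depth matching the genes that turned were Cxcl10 at -0.10, Hp at -0.14 (-0.0540 at resolution 2), Setbp1 at 0.21 and Slc12a2 at 0.32. Among list medians, gamma-delta markers in T-like cells were 0.0794 with cluster matching and CD4 markers 0.0347 without depth matching. MHC class I was 0.0215 with a test that pointed down at an expected Y count of 3. In monocyte or macrophage-like cells the cytotoxic list was -0.33 without depth matching and -0.00867 with doublets kept, and liver tumour genes -0.0512 without depth matching, -0.0231 with cluster matching and 0.0306, with a test that pointed down, at 10% mitochondrial UMIs. Tissue residency in B-like cells was -0.0511 at resolution 2, with a test that pointed up. MHC class II in neutrophil-like cells, with few members, was -0.44 without depth matching and -1.49 at 10% mitochondrial UMIs, both called, and -0.11 with doublets kept and -0.17 without T cell marker UMIs. Without each library, neutrophil-like lists ranged from -0.0409 to 0.34 for their own markers, from -0.48 to 0.0137 for mitochondrial transcripts and from -0.24 to 0.00473 for ribosomal proteins.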

Other observations

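The tests of cluster mixing, of chromosome loss in T-like cells, of counting, RNA loss and chromosome loss in Kupffer-like cells, of IL-17 cluster shares and of numbers of genes were chosen only after the result was seen. T-like states differed between libraries. The Gzmk and Pdcd1 cluster held 32.4%, 14.6% and 30.1% of T-like cells in libraries 1, 2 and 3, and the Il4 and Zbtb16 cluster 14.2%, 27.8% and 7.14%. The regulatory cluster held 20.6%, 13.97% and 18.5%, the Gzmm cluster 11.9%, 16.5% and 13.7%, the Igfbp4 cluster 8.04%, 10.0% and 6.58%. The Il23r cluster held 6.32%, 5.19% and 9.33%, the Gzma cluster 2.11%, 8.42% and 3.82%, the Il17a cluster 3.16%, 2.47% and 7.87% and the Ifit3 cluster 1.27%, 1.00% and 2.89%. Tox, a transcription factor of exhausted T cells, stood at 906 ± 197 CPM (SD, n = 3) in the Gzmk cluster with Pdcd1 at 142 ± 17.7, and at 750 ± 238 in the regulatory cluster with Pdcd1 at 86.6 ± 17.2. Over classes, Tox was also high in NK or innate lymphoid-like cells, at 676 ± 105 against 471 ± 157 in T-like cells. Cd274, which encodes the PD-1 ligand, stood at 392 ± 188 in neutrophil-like, 232 ± 50.8 in B-like and 103 ± 4.94 in T-like cells. The inhibitory receptor genes Havcr2 and Lag3 were highest outside T-like cells, with Havcr2 at 204 ± 25.6 in conventional dendritic-like cells and Lag3 at 117 ± 7.58 in plasmacytoid dendritic-like cells. T-like cells had 14.9 ± 12.5 and 8.39 ± 4.86. Of the lipid genes, Plin2, a lipid droplet protein, stood at 365 ± 63.0 in monocyte or macrophage-like and 320 ± 43.7 in neutrophil-like cells, Lpl at 957 ± 628 in Kupffer-like cells, and the desaturase gene Scd1 at 267 ± 54.7 in B-like cells. These levels were not tested between classes.

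The Y genes were detected together more often than matched sets. In T-like and conventional dendritic-like cells, the tables argue against a mixture of clusters as the whole cause, since the odds ratio with depth bins inside clusters was 1.16 (95th percentile of matched sets 1.12) and 1.44 (1.19), though in T-like cells by a margin barely above the SD between libraries. In monocyte or macrophage-like cells the odds ratio with bins inside clusters, 1.15 (1.12), was also past the 95th percentile. The margin was less than the SD between libraries, so a mixture stays open there too. A cell state or RNA quality that lowers Y genes and X copies alike may contribute in conventional dendritic-like cells. Pairs of a Y gene with an X copy had an odds ratio of 1.22 there (95th percentile 1.14). In neutrophil-like cells it was 1.16, near the median of matched pairs, 1.17 (95th percentile 1.41). That argues only against a state particular to these genes, since a state that lowers many genes would raise the matched pairs too. How large an effect this comparison could see was not measured. A state that lowers Y genes and X copies alike stays open in T-like cells, at 1.095 (1.095). It also stays open in monocyte or macrophage-like cells, at 1.11 (1.099), since both values lie too near the limit. Loss of the chromosome in a fraction of T-like cells also stays open, since only 104 cells expect at least 5 Y UMIs and the exact Poisson p for those without any was 0.268; no other biological explanation was tested.

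The Kupffer-like cluster had few Y transcripts, with 7 Y UMIs among 116924, or 59.9 CPM (exact interval 24.1 to 123), in 7 of 46 cells, while the unnamed cluster led by C1qa, a Kupffer list gene, had 255 CPM. Counting error is argued against by the exact test against monocyte or macrophage-like cells (p = 2.38e-06). Loss of RNA that lowers Y genes and X copies alike may account for it, since the X copies were low as well and Y against X copies gave a Fisher exact p of 0.421 (odds ratio 0.644, interval 0.230 to 1.59). Loss of the chromosome in these cells stays open, with X copies at 171 CPM against 456 in monocyte or macrophage-like cells and an interval for the ratio that includes 1. A low level of most genes of that abundance also stays open, since the ratio of the Y sum, 0.242, lay beside the 5th percentile of matched sets, 0.244, and the top 20 genes took 24.1% of UMIs against 14.2%; no other biological explanation was tested.

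The genes that differ between Y-negative and Y-positive cells may partly reflect how cells were sorted by status. In T-like cells, a different share of IL-17 clusters is a candidate explanation for the IL-17 genes, since Il17a stood at -0.13 with cells matched on cluster. These clusters had the most Y transcripts, so the split by Y UMIs itself tends to make their share differ. Fewer UMIs of any gene of that level is a candidate for the ribosomal rise, which 4 of 20 matched autosomal splits reached. The number of genes was reached by 5, 8 and 10 of 20 such splits in T-like, monocyte or macrophage-like and conventional dendritic-like cells. The medians of the splits were lower, at 174, 77.5 and 81.5. They ranged from 11 to 941, from 1 to 1356 and from 2 to 416, so the level of the chosen genes alone does not set the number. Fewer UMIs of any gene of that level therefore stays open for the number of genes. No biological explanation was tested.

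For the Y genes, edgeR called 4 of 7 classes against T-like cells and at most 1 in any other of 100 splits of the sums within libraries. It called 5 of 9 T clusters, against at most 1 in the others. In each case 1 of 100 splits, the real one, did as well. These splits exchanged whole class or cluster sums, on a random part of the genes. Differences between cell types thus entered their spread and made calls less likely, so they cannot exclude chance. For Y-negative against Y-positive cells without the library as a block, the 10 splits of 6 sums are too few for a share under 0.05. The real split called 0 genes in each of 6 classes, and the highest other called 23 in T-like, 81 in NK or innate lymphoid-like, 40 in B-like, 51 in monocyte or macrophage-like, 19 in conventional dendritic-like and 1 in neutrophil-like cells. With the library as a block, the 4 splits that part both statuses of every library gave 385 in T-like cells against a highest other of 9, 264 against 12 in monocyte or macrophage-like, 101 against 1 in conventional dendritic-like, 0 against 0 in NK or innate lymphoid-like, 1 against 4 in B-like and 1 against 2 in neutrophil-like cells. The other splits exchange the statuses of 1 library.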
